A study of Mus musculus with 3 samples.

How the data were processed

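The series holds 3 single-cell RNA libraries of the mouse glioblastoma line KR158, prepared per the labels with the Chromium Single Cell 3′ v3 kit, with collection on day 5 after lentiviral transduction per the series description. The labels' treatment protocol instead has a passage without puromycin on that day, until library preparation. One library is of empty vector cells, one mixes dP-EV cells with spleen dendritic cells and one mixes dP-mF3 cells with empty vector cells, and 4T1 cells are in each per the labels. Each library is a group of its own, taken from the sample titles.

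The deposited matrices hold raw UMI counts per gene and barcode, not normalized, written by Cell Ranger 5.0.0 per the file headers. STAR, Seurat 3.2.2 and the builds GRCm39 and mm39 are named in the submitters' processing notes. The way barcodes were called as cells is not given in the sources used here. The deposited features are 22592, of which 13 are mitochondrial genes and 10 are vector and reporter features added by the authors (puromycin and ampicillin resistance, luciferase, EGFP, the vector pSF-simple, and features named for introduced and endogenous Spi1 and Id2). The deposited cell metadata give UMI counts per barcode and, as other columns, the library and 1 of 22 clusters from the authors' clustering of an integrated object, without cell type names. Of the 28537 barcodes 7 have no metadata, and the metadata totals differ from the matrix totals by at most 104 UMIs. The deposited matrix of the whole series was compared with the 3 library matrices side by side and differed in 0 entries. Its barcode suffixes 1, 2 and 3 stand for the dP-mF3, dP-EV and empty vector libraries, unlike the order in the sample descriptions, so libraries were taken from each library's own matrix and from the library name in the metadata. Of the feature identifiers 22477 were found in the reference name table, and 1 listed gene, Mx1, is not among the features. The reference annotation used for names is of another build, GRCm38, so no coordinates were used.

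Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept, which left out 14, 129 and 168 barcodes of the empty vector, dP-EV and dP-mF3 libraries. The median mitochondrial share was 3.68%, 5.00% and 4.59%. Doublets were kept, because Scrublet (in scanpy, expected rate 6%, 30 components) called 0, 5 and 0 barcodes, so few among the 22378 barcodes of the empty vector library that the caller did not work on it. As an alternative the barcodes at or above the score that bounds the highest 6% (1656, 152 and 207) were left out. Tied scores were included, so these are more than 6% of the barcodes, most of all in the empty vector library. The authors' clusters were named from fixed markers. For each cluster of at least 10 cells, the 10 genes with the highest ratio to the mean of the other clusters, among genes of at least 20 CPM, were compared with markers of 4T1, KR158 glioma, spleen dendritic, mature dendritic, plasmacytoid dendritic, B, T, NK, macrophage, monocyte-neutrophil and erythroid cells. A name needed at least 3 markers at 10 CPM or more. A cluster whose leading genes held more markers of another class, or whose median UMIs were under 1/3 of its library's without markers of its class among the 10 genes, stayed without a name. KR158-derived-like clusters also had to have under 5% of the summed 4T1 marker level of the 4T1-like cells in every library, a limit set after the data were seen. The clusters were built by the authors on integrated values, so the classes carry the authors' parameters, which are not given in the sources used here.

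UMIs were summed over the cells of a class and library and divided by their total to give CPM. With 1 library per group, no test was made. For each gene the value is log2 of the ratio of CPM + 1 (pseudocount 1), with exact Poisson 95% intervals for each CPM and an exact conditional interval for the ratio. A gene counts as higher or lower at a ratio of at least 2-fold, at least 10 CPM in the higher class and intervals that do not overlap. Against 0 UMIs a fold is given as a lower bound, against the level of 3 UMIs over the class, and no fold is given where both classes are at or under that level. Listed genes count as measured at 1 CPM or more in either class, and a list's median is also given with genes at 0 UMIs at that bound where it differs. Each median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The genes named are the 4 factors, up to 3 members of each list with the highest CPM, and the 8 largest and 8 smallest ratios among genes of at least 50 CPM in the higher class, leaving out predicted, Rik, mitochondrial and ribosomal protein genes. The shares of cells with Ptprc or an MHC class II gene were planned. The vector features, the levels of Ptprc and the genes shown by Spi1 level were chosen after their values were seen. Genes of multigene families (MHC, Ifit, Bcl2a1, histone, Prl2c and Slfn genes) can share UMIs, so their single values are uncertain.

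The 22 lists, fixed by name, cover the factors, MHC class II, MHC class I, pan-leukocyte, conventional dendritic cell, dendritic cell maturation, macrophage, phagocyte oxidase and lysosome, interferon response, NF-kB and cytokine, glial progenitor, matrix and cytoskeleton, cell cycle, stress and immediate early, epithelial (4T1), B cell, T cell, NK cell, plasmacytoid dendritic cell, neutrophil and monocyte, splenic macrophage and erythroid genes. The maturation, matrix, glial and epithelial lists share members with the markers that named the clusters. The lists, the markers, the rule for named genes, the comparisons and the alternatives were fixed before the data were examined. Other choices, among them the naming limit above, the split by Spi1, the alternatives called added and most tests of the closing section, came after.

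Shares of cells with a UMI carry exact Clopper-Pearson 95% intervals and were repeated after thinning each cell to 3000 UMIs. The depth behind them is the total per library of 65063198, 170077419 and 203023038 UMIs, and 3 UMIs correspond to 0.234 CPM in empty vector, 0.0196 in dP-EV and 0.0161 in dP-mF3 KR158-derived-like cells, 3.24 in mature dendritic cell-like cells and 2.10, 0.237 and 0.261 in the 4T1-like cells. UMI intervals cover counting error and not differences between cultures, droplets or sorts. Free RNA in droplets gives UMIs in cells that do not express a gene, so the 4T1-like cells of each library are given as a yardstick of what comes with the library. They serve less well for Irf8, of which 7.39%, 44.0% and 54.5% of them had a UMI in the 3 libraries. The split by Spi1 counts UMIs of Spi1 and of the introduced-Spi1 feature in cells of at least 20000 UMIs.

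Alternatives were a stricter cell filter (at least 2000 genes, at most 10% mitochondrial UMIs), all barcodes with a class, median-of-ratios scaling, TMM factors from edgeR 4.0.16, the mean of per-cell CPM, a floor of 50 CPM or none, a 4-fold rule, a pseudocount of 5, lists with all members, and thinning. Added after the data were seen were the Scrublet scores above, the unnamed clusters as part of the control, Spi1-high cells alone, and clusters 4 and 12 left out. The calculation was tested on simulated counts for each of the comparisons, run on 22592 genes. It called 100 of 100 genes changed 3-fold in the comparisons of dP-EV and dP-mF3 with empty vector cells and with each other, 99 of 100 for dP-EV and 98 of 100 for dP-mF3 against spleen cells. It called 0 of 100 genes changed 1.5-fold in the first 3 comparisons and 2 of 100 in each spleen comparison, since these lie under the 2-fold rule. Of unchanged genes it called 0 of 7893, 0 of 8045 and 0 of 8209, and 52 of 8295 and 40 of 8371 in the spleen comparisons, none of them at 50 CPM or more. The first limit of 5 unchanged genes was passed in the spleen comparisons, whose reference is shallow, and was then replaced by 1%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, matplotlib 3.10.9 and R 4.3.3 were used. Cell cycle phases, trajectories and a new clustering were left out, and no values per cell were corrected for free RNA.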

Results

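Single-cell RNA sequencing was used to follow KR158, a mouse glioblastoma cell line, after lentiviral delivery of transcription factors that act in dendritic cell development. The question behind the libraries, as the series describes it, was whether such factors turn glioblastoma cells into antigen presenting cells that resemble dendritic cells. The first library held KR158 cells with an empty vector. The second held KR158 cells given dP-EV, where dP is PU.1 (the product of Spi1) without its PEST domain, mixed with spleen dendritic cells. The third held KR158 cells given dP together with mF3, a single construct carrying Irf8, Batf3 and Id2, mixed with KR158 cells of the empty vector arm. Cells of 4T1, a mouse mammary carcinoma line carrying GFP and luciferase, were added as an internal control. There was 1 library per group, so no difference between libraries has a replicate check, no test was made and no p-value is given.

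The empty vector library held 22392 barcodes and 65063198 UMIs (unique molecular identifiers, which count captured transcripts), with a median of 2350 UMIs and 1175 genes per barcode. The dP-EV mixture held 2550 barcodes and 170077419 UMIs, with medians of 53494 UMIs and 6793.5 genes, and the dP-mF3 mixture held 3595 barcodes and 203023038 UMIs, with medians of 43620 UMIs and 6315 genes. The labels say that 12000 cells were put on the instrument for each library, so the 22392 barcodes of the empty vector library cannot each be a separate cell. Expression is given as UMIs summed over a population and scaled by that population's total UMIs (CPM), with exact Poisson 95% intervals. Shares of cells carry exact Clopper-Pearson 95% intervals. All these intervals, and those of ratios, cover counting error only. "Higher" and "lower" mean at least a 2-fold ratio of CPM + 1, with at least 10 CPM in the higher population and intervals that do not overlap, which is a rule of size and not a test. Listed genes are measured from 1 CPM, so members under 10 CPM could not be called. Counts of list members can therefore miss changes of weakly expressed genes.

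The makeup of the libraries was read from the authors' 22 clusters, named by marker genes. Cells with glial and matrix genes such as Sox2 (a neural stem cell factor) and Sparc (a matrix glycoprotein), called KR158-derived-like, and below dP-EV cells, dP-mF3 cells or empty vector cells by library, were 2116 of the 22378 barcodes kept in the empty vector library, or 9.46% (9.08 to 9.85). They were 1983 of 2421 in the dP-EV mixture (81.9%, 80.3 to 83.4) and 3144 of 3427 in the dP-mF3 mixture (91.7%, 90.8 to 92.6). Cells with epithelial genes such as Epcam and Krt18, called 4T1-like, were 176, 159 and 154 barcodes, or 0.786% (0.675 to 0.911), 6.57% (5.61 to 7.63) and 4.49% (3.82 to 5.24). A cluster of 180 cells of the dP-EV mixture (7.43%, 6.42 to 8.55) was led by Ccr7, the receptor that guides mature dendritic cells to lymph nodes, and by Ccl22, a chemokine they secrete, and is called mature dendritic cell-like (cluster 18). No cluster met the naming rule for immature spleen dendritic cells, of which 600 were put in beside 600 mature ones. In the empty vector library 20086 barcodes (89.8%, 89.4 to 90.2), with a median of 2286 UMIs, stayed without a name and enter no comparison, and so did 99 barcodes of the dP-EV mixture (4.09%) and 129 of the dP-mF3 mixture (3.76%). Clusters without a name whose 4T1 marker level was at least 5% of that in 4T1-like cells, a limit set after the data were seen, held 89.7%, 2.48% and 0.642% of the barcodes of the 3 libraries.

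**Figure D1:**
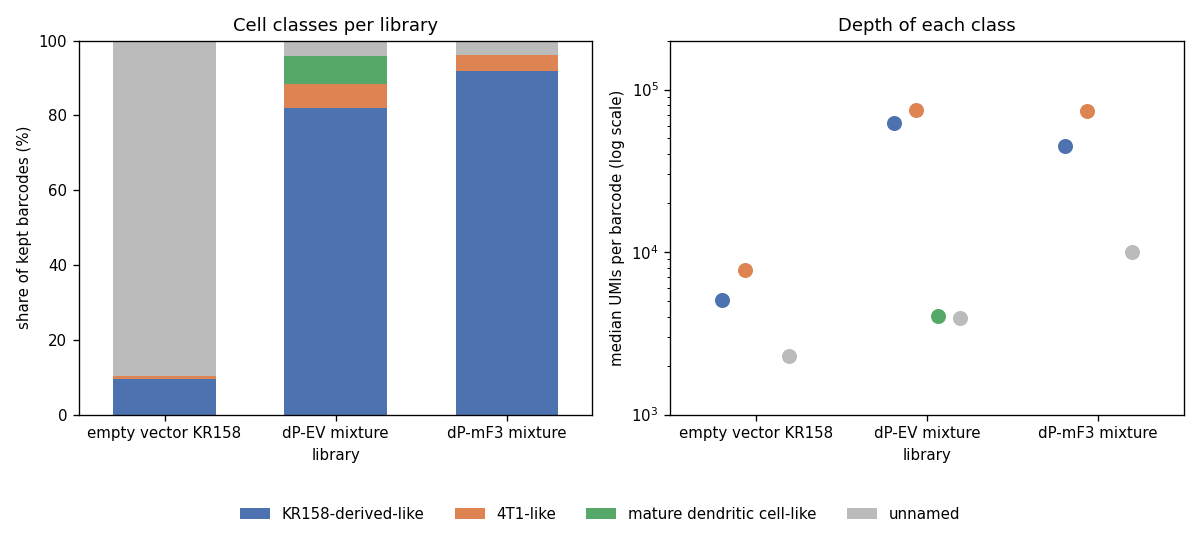
Left, share (percent) of the kept barcodes of each library that falls in each class; right, median UMIs per barcode of each class on a log axis. KR158-derived-like cells are 9.46%, 81.9% and 91.7% of the empty vector, dP-EV and dP-mF3 libraries, and the unnamed barcodes of the empty vector library have a median of 2286 UMIs.

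The labels give the cells combined for each mixture. The dP-EV mixture was assembled from 7142 cells sorted on the surface proteins CD45 and MHC class II, 26.2% of them taken as CD45-positive and 72.9% as MHC class II-positive, with 600 4T1 cells (6.71% of the 8942 cells combined) and 600 immature and 600 mature spleen dendritic cells. The dP-mF3 mixture was assembled from 13897 sorted cells, 72.2% CD45-positive and 39.3% MHC class II-positive, with 600 4T1 cells (3.87% of 15497) and 1000 empty vector cells (6.45%). The empty vector cells of the third library could not be separated from the others, so its KR158-derived-like class includes them. A column of the deposited cell metadata, whose meaning no source used here gives, has one value for both mixtures and another for the empty vector library. If it marks a batch, differences from the empty vector library lie along it too, and the 4T1-like cells and the split by Spi1 within a mixture separate these only in part. Most clusters of the class held cells of both mixtures, but cluster 4 held 84 dP-EV and 1507 dP-mF3 cells, cluster 12 held 429 and 23, and cluster 19 held 0 and 70. A cluster mostly of 1 library may be that library.

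The delivered factors were measured first, as a check of the labels. Spi1 (ENSMUSG00000002111) had 0 UMIs in empty vector KR158 cells, where 3 UMIs would have been 0.234 CPM. It reached 78.2 CPM (76.8 to 79.6) in dP-EV cells and 148 CPM (147 to 150.2) in dP-mF3 cells, at least 334-fold and at least 634-fold higher. Irf8 (ENSMUSG00000041515), a factor required for conventional dendritic cells of type 1, was at 621 CPM (617 to 625) in the dP-mF3 mixture, 0.346 CPM (0.259 to 0.453) in dP-EV cells and 0.0781 CPM from 1 UMI in empty vector cells. Batf3 (ENSMUSG00000026630), its partner in that lineage, was at 24.5 CPM (23.8 to 25.2) in the dP-mF3 mixture, against 4.22 (3.90 to 4.56) in dP-EV cells and 4.22 (3.17 to 5.50) in empty vector cells. Id2 (ENSMUSG00000020644), an inhibitor of E proteins, was at 199.7 (198 to 202), 62.2 (61.0 to 63.5) and 20.5 CPM (18.1 to 23.2) in the same order. The puromycin resistance feature of the vector was at 4.76 CPM (3.64 to 6.12) in empty vector cells, 48.6 (47.5 to 49.7) in dP-EV cells and 92.9 (91.5 to 94.3) in dP-mF3 cells. A feature named for introduced Spi1 was at 3.53 CPM in dP-EV and 4.71 CPM in dP-mF3 cells with 0 UMIs in empty vector cells. Its endogenous counterpart had 0 UMIs in each. It also had 0 in mature dendritic cell-like cells, where Spi1 was at 109 CPM (101 UMIs), so its 0 is no measure of the cells' own gene. The counts of Spi1 itself do not separate the construct from that gene.

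**Figure D2:**
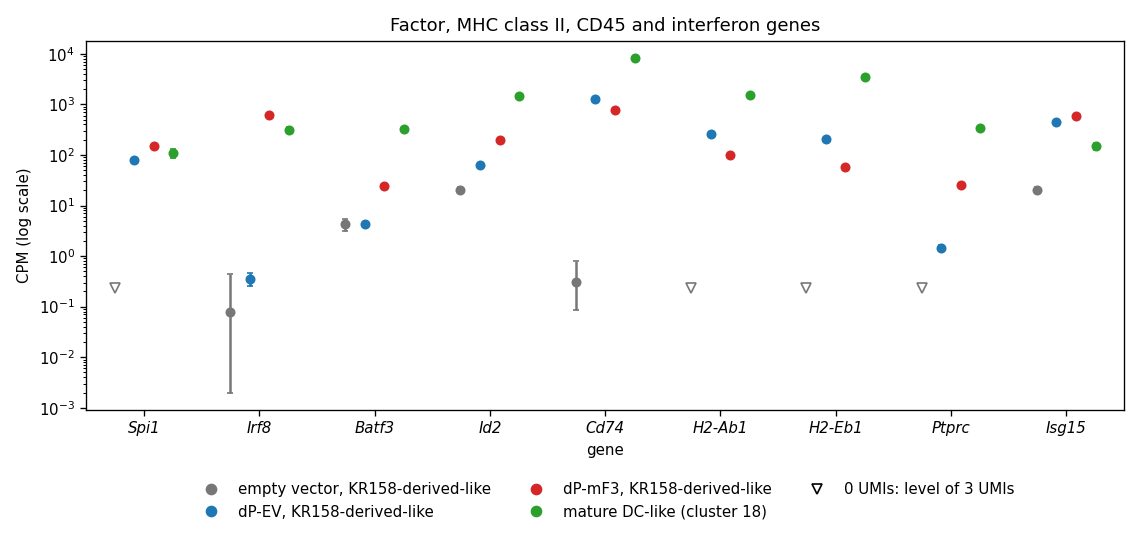
CPM on a log axis, with exact Poisson 95% intervals, of the delivered factors and of Cd74, H2-Ab1, H2-Eb1, Ptprc and Isg15 in KR158-derived-like cells of the 3 libraries and in mature dendritic cell-like cells; open triangles mark 0 UMIs, drawn at the level of 3 UMIs. Spi1 stands at 78.2 CPM in the dP-EV and 148 CPM in the dP-mF3 mixture, Irf8 at 621 CPM in the dP-mF3 mixture and 0.346 in dP-EV cells.

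To see what truncated PU.1 went with in the absence of mF3, dP-EV cells were compared with empty vector cells. Genes of antigen presentation on MHC class II had the highest median ratio of the measured lists. The sort acts on this rank, since 72.9% of the sorted dP-EV cells were taken as MHC class II-positive and the labels give no sort for the empty vector library. Cd74 (ENSMUSG00000024610), the invariant chain that chaperones class II molecules, was at 1263 CPM (1258 to 1269) against 0.312 (0.0851 to 0.800; 4 UMIs). The class II chains H2-Ab1, H2-Aa and H2-Eb1 were at 262 (259.8 to 265), 220.5 (218 to 223) and 203 CPM (200.3 to 205) against 0 UMIs. H2-Aa was at least 941-fold and H2-Eb1 at least 865-fold higher. Of the 11 class II genes, 9 were measured (at least 1 CPM in either population), 7 were higher and 0 lower. For MHC class I presentation 11 of 13 genes were higher. They included B2m, the class I light chain, at 9.48-fold (9.09 to 9.89), H2-K1 at 25.6-fold (23.4 to 28.1) and H2-D1 at 33.5-fold (30.4 to 36.9). All 15 measured interferon response genes were higher. Examples were Isg15, a ubiquitin-like antiviral protein, at 21.7-fold (442 against 20.4 CPM), Ifit1, a sensor of foreign RNA caps, at 79.7-fold (58.1 to 113) and Bst2 (tetherin) at 27.7-fold (25.5 to 30.2). Of the 15 NF-kB and cytokine genes 11 were higher, among them the monocyte chemokines Ccl2 at 35.1-fold (32.2 to 38.4) and Ccl7 at 6.58-fold (6.13 to 7.07).

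Fewer of the leukocyte identity genes counted as higher in the dP-EV cells, in part because many lay under the 10 CPM that a call needs. Among 10 measured pan-leukocyte genes 3 were higher. Ptprc, Coro1a, Laptm5, Tyrobp, Fcer1g and Was could not be called, at 1.45, 1.61, 2.26, 3.38, 1.21 and 5.65 CPM. In empty vector cells these genes had at most 0.312 CPM. Cd52, a small surface glycoprotein of lymphocytes and myeloid cells, was at 46.0 CPM against 0 UMIs, and the phosphatase Ptpn6 was 34.5-fold higher (15.8 to 94.1), while Arhgdib was at a log2 ratio of -0.06. Of the macrophage genes 4 of 9 were higher, including Lyz2 (lysozyme) at 52.1 CPM against 0 UMIs and the endosomal glycoprotein Cd68 at 28.0-fold (17.7 to 47.3). Lyz2 was also higher in 4T1-like cells, at a log2 ratio of 3.76, where Cd68 was at -0.96. The median of Lyz2 over dP-EV cells of at least 20000 UMIs was 0 CPM, also in those of at least 100 CPM of Spi1. Of the conventional dendritic cell genes 3 of 8 were higher, with the signal-regulatory receptor Sirpa at 2.96-fold (2.39 to 3.71) and the RNA sensor Tlr3 at 3.55-fold (2.69 to 4.78). Cadm1, an adhesion molecule of type 1 dendritic cells, was at 79.8 against 39.7 CPM. Dendritic cell maturation genes were higher for 2 of 11, and Fscn1, Cacnb3 and Relb had log2 ratios of -0.58, -0.15 and 0.61. Ccr7, Ccl22, Ccl17, Il15 and Cd83 could not be called, at 2.01, 1.90, 3.53, 6.95 and 2.78 CPM. In empty vector cells they were at 0, 0, 1.015, 0.625 and 0.156 CPM. Stress and immediate early genes were higher for 10 of 15, led by Hmox1, which degrades heme, at 17.0-fold (15.4 to 18.8). The glial list had 3 higher and 1 lower of 11, with Nes and Sox2 at log2 ratios of -0.47 and -0.09. Fabp7, a fatty acid binding protein of glia, was 289-fold higher (113 against 0.390 CPM), with a log2 ratio of 3.94 in 4T1-like cells and 89.9 CPM in dP-EV cells without a Spi1 UMI. The cell cycle list had 3 higher and 0 lower of 16. Matrix and cytoskeleton genes were lower for 6 of 18 and higher for 2. The smooth muscle proteins Tagln and Acta2 were 6.52-fold and 7.40-fold lower, with Vim, the intermediate filament vimentin, at a log2 ratio of 0.08. Phagocyte oxidase and lysosome genes had 1 member higher and 1 lower of 13.

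The largest ratios in dP-EV cells were also read outside the lists. Clec5a, a myeloid lectin receptor, was at 541 CPM (538 to 545) and Cd207 (langerin), a lectin of Langerhans cells, at 237 CPM (234 to 239), both against 0 UMIs. Slfn2 and the interferon-induced Ifi27l2a were 422-fold (205 to 1049) and 227-fold (172 to 307) higher. Lower in dP-EV cells were Crabp1, a retinoic acid binding protein, by 66.9-fold, Myl9, a regulatory light chain of myosin, by 7.20-fold, and the matrix Gla protein gene Mgp by 6.55-fold. Their log2 ratios in 4T1-like cells were -3.22, -3.06 and -1.36, and Crabp1 and Mgp are among the leading genes of the unnamed clusters 0 and 1 of the empty vector library.

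Median log2 ratios of the lists in dP-EV against empty vector cells were 7.04 for MHC class II, 4.91 for interferon response, 3.80 for MHC class I, 2.92 for NF-kB and cytokines (3.19 with genes at 0 UMIs set at the limit of 3) and 2.24 for macrophage genes. Each of these was above all 10000 random lists matched on expression (percentile 100), which describes these libraries and tests nothing. The medians were 1.92 for pan-leukocyte genes (3.22 with genes at 0 at their limit), 1.54 for maturation (1.71), 1.10 for conventional dendritic cell genes (1.52), 1.47 for stress, -0.02 for cell cycle, -0.09 for glial and -0.33 for matrix genes. All genes together had a median of 0.24, or 0.00 with median-of-ratios scaling. Of 8533 genes of at least 10 CPM in either class, 1023 were higher and 276 lower, 15.2% together. By the same rule, 778 of 7863 genes were higher and 75 lower in the 4T1-like cells of these libraries, 10.8% together. In dP-EV cells of at least 20000 UMIs without a Spi1 UMI, 748 of 8373 genes were higher than in empty vector cells and 227 lower, 11.6% together. Much of the 15.2% therefore cannot be credited to Spi1. In 4T1-like cells of the same 2 libraries, added as an internal control per the labels, the medians were 3.40 for MHC class II (2.19 with genes at 0 at their limit), 1.62 for interferon response, 1.37 for MHC class I, 1.37 for NF-kB and cytokines and -0.04 for matrix genes. Single genes also moved in the 4T1-like cells, with log2 ratios of 5.34 for Cd74, 5.32 for Clec5a, 4.31 for Ccl2, 3.70 for Ifit1, 3.27 for Hmox1, -3.20 for Acta2, -2.61 for Tagln and 0.20 for Isg15. All 6 lower matrix genes except Col6a1 were lower in the 4T1-like cells as well, which the median of that list does not show, with Col1a1 at -1.47 against -1.47 in dP-EV cells. Among all genes of at least 10 CPM in both comparisons, 682 were higher in dP-EV cells, and 285 of them (41.8%) were also higher in 4T1-like cells. Of 173 lower genes, 36 (20.8%) were also lower there. Of all 7317 such genes, 708 were higher and 69 lower in 4T1-like cells, so unrelated lists would share 66.0 and 1.63. The 4T1-like cells of the empty vector library held only 1431150 UMIs. H2-Eb1 and Psmb8 had 4T1 log2 ratios of 3.40 and 2.65 without being called. Genes not called in 4T1-like cells are therefore not shown to be free of a library difference.

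**Figure D3:**
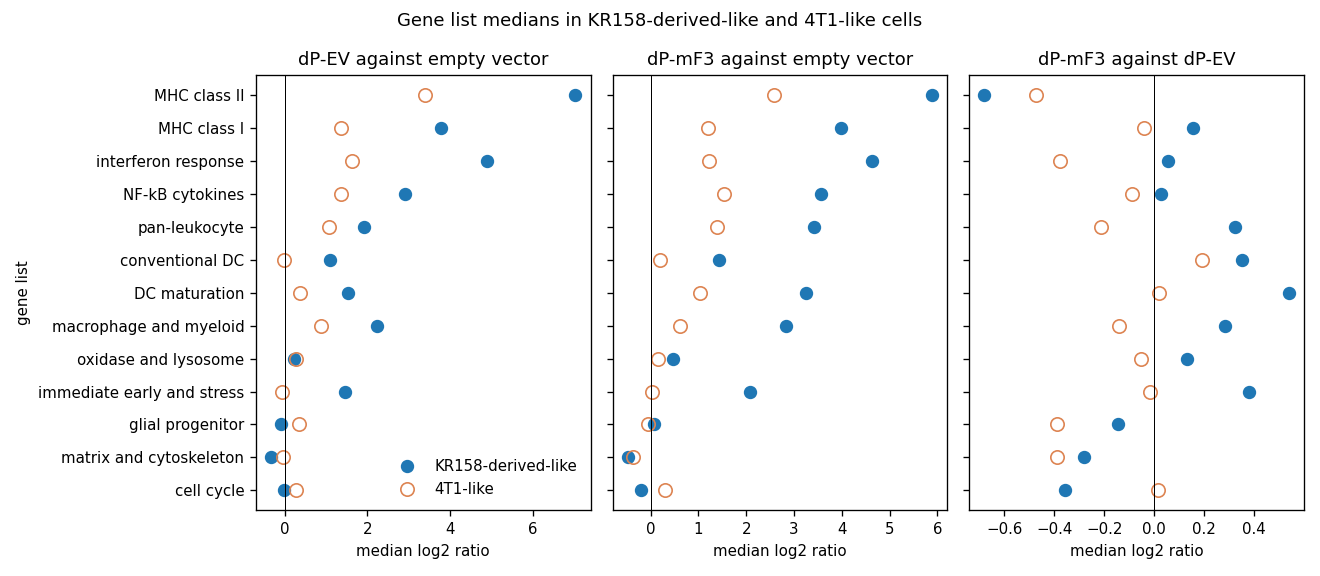
Median log2 ratio of CPM + 1 over the measured members of 13 gene lists in 3 comparisons of libraries; filled symbols are KR158-derived-like cells and open symbols the 4T1-like cells of the same libraries. For dP-EV against empty vector, MHC class II lies at 7.04 in KR158-derived-like and 3.40 in 4T1-like cells, and interferon response at 4.91 and 1.62.

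The same comparison for the 4 factors together set KR158-derived-like cells of the dP-mF3 mixture against empty vector cells. Class II genes were again among the genes far above the control, with Cd74 at 789 CPM (785 to 793) and H2-Aa and H2-Ab1 at 91.3 (89.9 to 92.7) and 99.4 CPM (98.0 to 101) against 0 UMIs. Of the measured class II members 8 of 9 were higher. MHC class I genes were higher for 11 of 13, with B2m at 10.6-fold (10.1 to 11) and H2-D1 at 36.0-fold (32.7 to 39.7). Interferon response genes were higher for 15 of 15, among them Isg15 at 28.9-fold (25.6 to 32.8) and Ifit2, an antiviral RNA-binding protein, at 17.0-fold (14.9 to 19.4). Of the NF-kB and cytokine genes 12 of 13 were higher, with Ccl2 at 24.9-fold (22.8 to 27.2).

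Maturation genes were higher for 7 of 10 measured members in the dP-mF3 mixture, including the NF-kB subunit Relb at 3.27-fold (2.90 to 3.71), with log2 ratios of -0.91 for the actin bundler Fscn1 and -0.22 for Cacnb3. Pan-leukocyte genes were higher for 4 of 8, with Cd52 at 61.8 CPM against 0 UMIs and the tetraspanin Cd53 39.1-fold higher (21.2 to 81.5). The sort acts here too, as 72.2% of the sorted dP-mF3 cells were taken as CD45-positive. Of the macrophage genes 6 of 9 were higher, among them Cd68 at 29.0-fold (18.3 to 48.9) and Csf1r, the receptor for macrophage colony-stimulating factor, at 18.6-fold (10.4 to 37.3). Conventional dendritic cell genes were higher for 4 of 7, with Cadm1 at 2.57-fold (2.35 to 2.81) and Tlr3 at 4.59-fold (3.48 to 6.17). Stress genes were higher for 9 of 15, including Ddit3, a factor of the unfolded protein response, at 4.76-fold (4.50 to 5.03). Matrix genes were lower for 6 and higher for 3 of 18, with the collagen gene Col1a2 6.67-fold and Tagln 6.15-fold lower. The glial list had 2 higher and 1 lower of 11, with Sox2 at a log2 ratio of 0.07 and Fabp7 at 143 CPM, 367-fold higher. The cell cycle list had 2 higher and 0 lower of 16, and the phagocyte oxidase and lysosome list 2 higher and 1 lower of 14. Genes with the widest ratios included the chemokine Ccl6 at 232 CPM against 1 UMI, the survival gene Bcl2a1d at 195 CPM against 0 UMIs, at least 832-fold, and Slfn2 at 930.3-fold (452 to 2314). Crabp1 was 62.2-fold and Stmn2, a neuronal tubulin-binding protein, 9.32-fold lower, with log2 ratios of -2.90 and -3.20 in 4T1-like cells, and both are leading genes of the same unnamed clusters.

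List medians for dP-mF3 against empty vector cells were 5.88 for MHC class II (6.18 with genes at 0 UMIs at their limit), 4.63 for interferon response, 3.99 for MHC class I, 3.57 for NF-kB and cytokines (3.65), 3.41 for pan-leukocyte (4.22), and 3.25 for maturation genes. They were 2.83 for macrophage (3.19), 2.08 for stress and 1.43 for conventional dendritic cell genes. The medians were -0.48 for matrix, -0.21 for cell cycle and 0.07 for glial genes, with 0.26 for all genes. In 4T1-like cells of these libraries the medians were 2.57 for MHC class II, 1.22 for interferon response, 1.21 for MHC class I, 1.54 for NF-kB and cytokines, 1.03 for maturation, 0.03 for stress and -0.36 for matrix genes. In the same cells Tagln, Col1a2, Ccl2 and Isg15 had log2 ratios of -4.83, -3.17, 3.77 and -0.31, and all 6 lower matrix genes except Col6a1 were lower there as well. Among all genes of at least 10 CPM in both comparisons, 888 were higher in dP-mF3 cells, and 261 of them (29.4%) were also higher in 4T1-like cells. Of 209 lower genes, 38 (18.2%) were also lower there. Of all 7267 such genes, 603 were higher and 80 lower in 4T1-like cells, so unrelated lists would share 73.7 and 2.30. The shallow 4T1-like cells of the empty vector library limit these calls too, so the other genes are not shown to be free of a library difference.

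What mF3 went with, beyond dP, was read from the dP-mF3 mixture against dP-EV cells, both of them sorted mixtures. Irf8 was 1794-fold (1372 to 2395), Batf3 5.81-fold (5.35 to 6.32) and Id2 3.21-fold (3.14 to 3.28) higher, and Spi1 had a ratio of 1.90 (1.86 to 1.94), under the 2-fold rule on CPM + 1. Class II genes were lower for 3 and higher for 1 of 9 measured members. The class II chains H2-Eb1, H2-Ab1 and H2-Aa were 3.49-fold, 2.64-fold and 2.41-fold lower, and Cd74 was at 789 against 1263 CPM, a log2 ratio of -0.68. In the 4T1-like cells the same genes had log2 ratios of -1.39, -0.47, -1.30 and -1.19, and the sort took 72.9% of dP-EV and 39.3% of dP-mF3 cells as MHC class II-positive.

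Maturation genes were higher in the dP-mF3 mixture for 6 of 12 measured members, among them Relb at 2.11-fold (2.04 to 2.18). Ptprc, which encodes the leukocyte antigen CD45, was at 25.6 CPM (24.9 to 26.4) against 1.45 (1.27 to 1.65), where 72.2% of the dP-mF3 and 26.2% of the dP-EV cells had been sorted as CD45-positive. Ccr2, the receptor for Ccl2, was 51.4-fold higher (40.0 to 67.2), and Vcam1, an adhesion molecule, 2.33-fold (2.27 to 2.40). The survival genes Bcl2a1d and Bcl2a1b, near-identical copies that can share UMIs, were 17.6-fold (16.8 to 18.5) and 13.4-fold (12.7 to 14.1) higher. Also higher were the secreted factors Ifnb1 (interferon beta) at 9.06-fold (8.54 to 9.61), Il6 at 5.42-fold (5.16 to 5.70) and Ccl6 at 13-fold (12.5 to 13.5). Interferon response genes were higher for 3 and lower for 1 of 15, with Ifit2 2.44-fold higher and Ifit1 2.17-fold lower (log2 -1.75 in 4T1-like cells). The alarmin gene Il33, the decorin gene Dcn and Grem1, which encodes a bone morphogenetic protein antagonist, were 3.15-fold, 2.53-fold and 2.25-fold lower, with log2 ratios of -2.44, -3.59 and -1.75 in 4T1-like cells.

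The other lists were counted in the same way. Of the MHC class I, glial, matrix and cell cycle genes no measured member was higher or lower, of 13, 10, 18 and 16, with medians of 0.16, -0.15, -0.28 and -0.36. The median was -0.68 for MHC class II (below all random lists, percentile 0; -0.47 in 4T1-like cells) and 0.54 for maturation (percentile 100; 0.02 in 4T1-like cells). Stress genes were higher for 2 of 15 and NF-kB and cytokine genes higher for 3 and lower for 2 of 15. Of 8604 genes of at least 10 CPM in either class, 151 were higher and 26 lower, 2.06% together. Among the 7258 genes at that floor in 4T1-like cells too, 2 of 43 higher genes (4.65%) were also higher in 4T1-like cells. Of 11 lower genes, 5 (45.5%) were also lower there, where 3 genes in all were higher and 30 lower. Without clusters 4 and 12, a comparison added after the data were seen, 9 list members were higher and 0 lower, against 23 and 6 with them.

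Spleen dendritic cells are the reference for the state the factors were meant to induce. The dP-EV cells (median 62587 UMIs) were set against the mature dendritic cell-like cells of the same library, which had 180 cells, a median of 4040.5 UMIs and 926465 UMIs in all. Cd74 was at 1263 against 8308 CPM (8123 to 8496), 6.58-fold lower. In all, 8 of 10 class II genes and 11 of 13 class I genes were lower. Maturation genes were lower for 14 of 15, with Ccr7 at 2.01 against 3386 CPM, Relb 40.3-fold and Fscn1 8.35-fold lower. Ccr7, Fscn1 and other genes of this list also served to name the cluster. Pan-leukocyte genes were lower for 13 of 15, such as Cd52 by 23-fold. Conventional dendritic cell genes were lower for 5 and higher for 3 of 13. The dendritic cell lineage genes Zbtb46 (a transcription factor) and Flt3 (a growth factor receptor) were 172-fold and 1254-fold lower, while Cadm1 was 2.55-fold higher (1.77 to 3.81). Irf8, Batf3 and Id2 were 904-fold, 77.3-fold and 23.7-fold lower in dP-EV cells, and Spi1 had a log2 ratio of -0.47.

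Genes of the starting line stayed above the spleen cells. All 18 measured matrix genes were higher in dP-EV cells, with Sparc at 7.0-fold (6.05 to 8.16) and Vim at 3.53-fold (3.32 to 3.77). So were 6 of 10 glial genes, with Nes, a neural intermediate filament, at 10.7-fold (6.46 to 19), and 15 of 16 cell cycle genes, with Top2a (topoisomerase) at 9.69-fold (7.24 to 13.3). Interferon response genes were higher for 10 and lower for 3 of 15, with Isg15 at 2.99-fold (2.53 to 3.56). Macrophage genes were higher for 2 and lower for 3 of 11, with Lyz2 4.38-fold higher (2.45 to 8.79). That ratio is of sums, and the median of Lyz2 over dP-EV cells of at least 20000 UMIs was 0 CPM at every Spi1 level. In the same order, the counts were 3 and 6 of 15 phagocyte oxidase and lysosome genes, 5 and 5 of 15 NF-kB and cytokine genes, and 7 and 2 of 15 stress genes. The medians were -3.86 for MHC class II, -1.49 for MHC class I, -5.46 for maturation, -4.49 for pan-leukocyte, -1.66 for conventional dendritic cell (-1.86 with genes at 0 UMIs at their limit), 1.92 for interferon response, 2.97 for matrix and 2.19 for cell cycle genes. All genes together had a median of 0.63, or 0.15 with median-of-ratios scaling. Of 9116 genes of at least 10 CPM in either class, 3575 were higher and 1506 lower, 55.7% together.

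The KR158-derived-like cells of the dP-mF3 mixture, from another library, were set against the same spleen cells. Irf8 was at 621 against 313 CPM (278 to 351), a log2 ratio of 0.99 and so within the 2-fold rule, and Batf3 and Id2 were 13.3-fold and 7.37-fold lower. Class II genes were lower for 9 of 10, with Cd74 by 10.5-fold and H2-Aa by 39.0-fold. Maturation genes were lower for 14 of 15, with Ccr7 at 0.0429 CPM against 3386 and Relb 19.1-fold lower, and pan-leukocyte genes for 13 of 15. MHC class I genes were lower for 8 of 13. Conventional dendritic cell genes were lower for 6 and higher for 3 of 14, with Cadm1 3.26-fold higher (2.27 to 4.88) and Zbtb46 83.7-fold lower. Ifnb1 was at 72.1 CPM (70.9 to 73.3) against 0 UMIs, at least 22.3-fold higher, and Vcam1 was 19.1-fold higher (8.18 to 58.8). Matrix genes were higher for 18 of 18 and interferon response genes for 10 of 15. The medians were -4.59 for MHC class II, -4.82 for maturation, -4.07 for pan-leukocyte (-4.35 with genes at 0 UMIs at their limit), 3.01 for matrix and 2.22 for interferon response genes, and all genes had a median of 0.67. Of 9184 genes of at least 10 CPM in either class, 3597 were higher and 1395 lower, 54.4% together.

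The surface proteins used for the sort were then followed at the level of single cells. Ptprc had a UMI in 34.4% (32.8 to 36.1) of KR158-derived-like cells of the dP-mF3 mixture, in 5.85% (4.86 to 6.97) of dP-EV cells. It had one in 0 of 2116 empty vector cells, which allows up to 0.174%, and in 64.4% (57.0 to 71.4) of mature dendritic cell-like cells. In 4T1-like cells, which should lack it, the share was 0.629% (0.0159 to 3.45) in the dP-EV and 7.14% (3.62 to 12.4) in the dP-mF3 mixture. Median depths were 75295 and 73833 UMIs in these 4T1-like cells, against 62587 and 45089 in the KR158-derived-like cells and 5088 in empty vector cells. A UMI of any MHC class II gene was found in 88.0% (86.5 to 89.4) of dP-EV cells and 62.0% (60.3 to 63.7) of dP-mF3 cells. The share was 84.9% (78.4 to 90.1) and 46.1% (38.1 to 54.3) in their 4T1-like cells, 0 of 2116 empty vector cells and 92.8% of mature dendritic cell-like cells. Cells were then thinned to 3000 UMIs, which left out 430 empty vector, 7 dP-EV, 36 dP-mF3 and 24 spleen cells and 22, 0 and 1 of the 4T1-like cells. The thinned Ptprc share was 7.56% (6.66 to 8.55) in dP-mF3 and 0.557% (0.278 to 0.994) in dP-EV cells, with 0 in the 4T1-like cells of both mixtures. The thinned class II share was 40.0% (37.8 to 42.2) in dP-EV, 25.2% (23.7 to 26.8) in dP-mF3, 10.7% and 3.27% in their 4T1-like cells and 92.9% in mature dendritic cell-like cells. The gates act on these shares, as they took 26.2% of dP-EV and 72.2% of dP-mF3 sorted cells as CD45-positive and 72.9% and 39.3% as MHC class II-positive.

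Within each mixture, cells differed in Spi1, and a comparison added after the data were seen split the KR158-derived-like cells of at least 20000 UMIs by its level. No Spi1 UMI was found in 498 dP-EV and 652 dP-mF3 cells, under 100 CPM in 863 and 1006, and at least 100 CPM, here Spi1-high, in 440 and 1065. Median depths in that order were 71172, 86819 and 41537 UMIs in dP-EV and 59157, 75014 and 35529 in dP-mF3 cells. Spi1-high is a range and not a cell type, and 101 of 1801 dP-EV and 170 of 2723 dP-mF3 cells lay between 80 and 120 CPM, near its boundary. The dP-mF3 cells without a Spi1 UMI can include empty vector cells mixed into that library. Ratios to them are therefore not among transduced dP-mF3 cells alone. Among dP-EV cells, 7 of 9 class II genes were higher in Spi1-high cells than in those without a Spi1 UMI. H2-Eb1 was at 722 against 31.3 CPM, and Ciita, the master regulator of class II transcription, was 29.2-fold higher (23.8 to 36.3). Over single cells, the median CPM of Cd74 was 3842 in the Spi1-high and 35.6 in the cells without a Spi1 UMI, that of H2-Ab1 508 and 10.8, and that of Ptprc 0 in both. Among dP-mF3 cells, Irf8 was 56.1-fold (53.3 to 59.0), Batf3 12.9-fold (11.3 to 14.9) and Ifnb1 149-fold (118 to 191) higher in Spi1-high cells, with 8 of 9 class II and 6 of 11 maturation genes higher. Median CPM over cells was 1106 against 17.7 for Irf8, 935 against 27.5 for Cd74, 31.0 against 0 for H2-Ab1 and 0 in both for H2-Eb1, Ciita and Ifnb1. Cell cycle genes were lower for 4 of 16 in dP-EV and 13 of 16 in dP-mF3 Spi1-high cells, and matrix genes for 7 and 8 of 18, with Col1a1 6.31-fold lower in the dP-mF3 mixture.

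**Figure D4:**
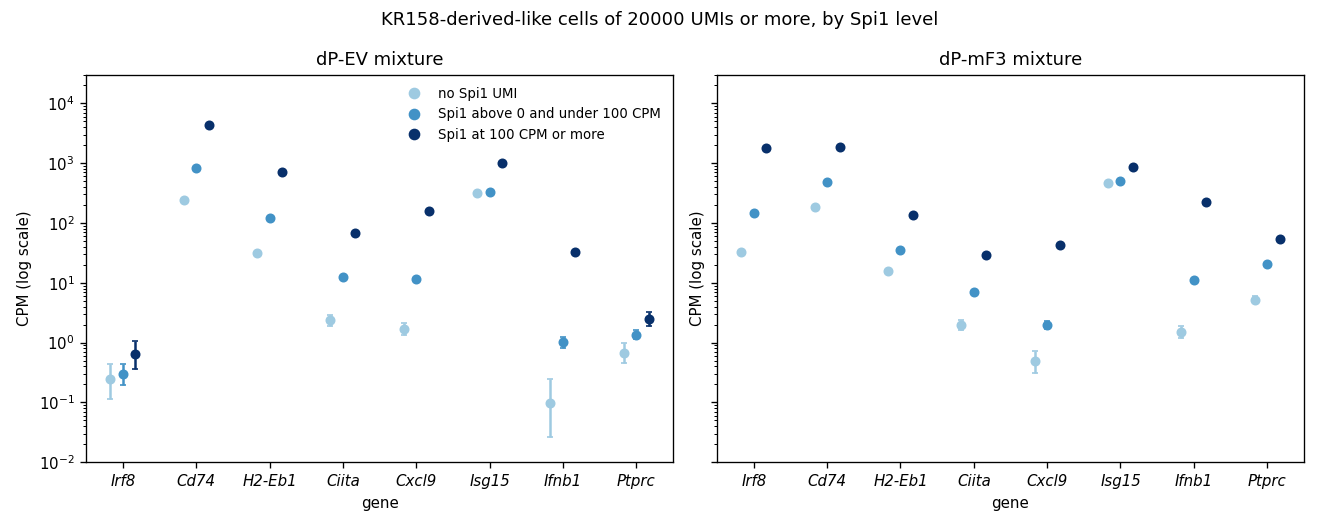
CPM on a log axis of Irf8, Cd74, H2-Eb1, Ciita, Cxcl9, Isg15, Ifnb1 and Ptprc, with exact Poisson 95% intervals, in KR158-derived-like cells of each mixture with no Spi1 UMI, under 100 CPM and at least 100 CPM of Spi1. H2-Eb1 goes from 31.3 to 722 CPM in dP-EV cells, and Irf8 from 32.3 to 1813 CPM in the dP-mF3 mixture, whose cells with no Spi1 UMI can include empty vector cells.

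Spi1-high cells of the 2 mixtures were also set against each other. The class II genes were lower in the dP-mF3 mixture for 7 of 9, with H2-Eb1 5.38-fold lower, and interferon response genes lower for 6 and higher for 2 of 15, with Ifit1 5.88-fold and Rsad2, an antiviral enzyme, 5.60-fold lower. Ptprc was at 53.3 CPM (51.3 to 55.4) against 2.5 (1.90 to 3.23), and maturation genes were higher for 6 of 12. Cell cycle genes were lower for 4 of 16 and matrix genes for 6 of 18. The sort gates, which differed between the mixtures, act on these cells too.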

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

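Of the tests in this part, those on the spread of 4T1 marker UMIs were written before their result was seen, and the share of deep barcodes without them, the test of clusters 2 and 13 and all tests on the vector feature were chosen only after.

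In the dP-EV mixture, a vector feature that the comparisons do not use, named Exo_ID2_Rev, had 492 UMIs in KR158-derived-like cells (3.21 CPM, 2.94 to 3.51), above its 0 UMIs in empty vector cells, although the labels give these cells no Id2 construct. What sequence it holds is given in no source used here, and it had 4828 UMIs in dP-mF3 cells (25.9 CPM, 25.1 to 26.6) and 3 in 4T1-like cells of the dP-EV mixture. Carry-over from the dP-mF3 mixture is argued against by Irf8, since 53 UMIs were observed where 11813 would have come along, a ratio of 0.00449 (0.00336 to 0.00587). Reads of the cells' own Id2 are argued against by the feature's ratio to Id2 UMIs, which was 11.4 times (3.89 to 55.7) that in 4T1-like cells. Sequence shared with the Spi1 construct remains a candidate explanation, as the feature was 19.1-fold (12.6 to 30) higher in Spi1-high dP-EV cells than in those without a Spi1 UMI. The puromycin resistance feature differed likewise, at 184 against 6.97 CPM. The contrast therefore cannot tell sequence of the Spi1 construct from other vector sequence, and no biological explanation was tested.

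In the empty vector library 20086 barcodes stayed without a name and outside the comparisons, with 4T1 marker levels of 9.34%, 10.6%, 9.78% and 11.1% of those in 4T1-like cells in clusters 0 to 3, against under 1% in the named KR158-derived-like clusters, while cluster 0 was led by Stmn2, Mgp and Igfbp6. The naming limit of 5%, set after the data were seen, fixes this contrast in part. A 4T1 cell under the same barcode as another cell would give these UMIs to few barcodes, but their variance over barcodes was 1.15 times that of an even spread in cluster 0. A simulation that placed the marker UMIs of cluster 0 in a random 1 in 10 of its barcodes gave 12. The clusters were built on expression, so barcodes with a 4T1 cell may have gone to other clusters, which the simulation does not mimic. The spread therefore speaks only for the barcodes left in cluster 0. In the named KR158-derived-like cells the variance was 2.52 times that of an even spread. In clusters 2 and 13, at up to 1.92, a 4T1 cell beside another cell could not be decided. The even spread in cluster 0 met what was written beforehand for free RNA, which stays a candidate explanation, though not in a like amount in every droplet, since 56.9% (54.4 to 59.4) of the 1547 deepest barcodes, taken whatever their cluster, held no marker UMI against 32.2% (31.2 to 33.2) in it. KR158 glioma markers were present too, with 12 at 10 CPM or more in each of clusters 0 and 1, against 9 in the 4T1-like cluster. The puromycin resistance feature was at 4.15 CPM (3.61 to 4.75) in the unnamed barcodes. It was at 4.76 CPM (3.64 to 6.12) in the named KR158-derived-like cells and 0.699 CPM, from 1 UMI, in the 4T1-like cells. The EGFP and luciferase features, for genes that 4T1 carries, were at 1.22 and 3.19 CPM in the unnamed barcodes. They were at 12.6 and 42.6 CPM in the 4T1-like cells of this library, and at 0 and 0.0781 CPM in its KR158-derived-like cells. The library has 22392 barcodes for the 12000 cells that the labels say were put on the instrument, so many barcodes cannot be separate cells. How KR158 and 4T1 transcripts came together in the unnamed barcodes stays open beyond that, and no biological explanation was tested.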

How the results depend on the processing

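The Scrublet scores, Spi1-high cells alone, the unnamed clusters in the control and clusters 4 and 12 left out were chosen only after the results were seen, the others beforehand. Of the main counts, levels and shares, 164 values under the alternatives set beforehand stayed within their counting interval or 1.5 times their count and 32 moved, and under added ones 32 stayed and 7 moved. Of the values for single genes and lists, 1963 stayed, 1375 moved and 5 reversed under the alternatives set beforehand, and 505 stayed, 494 moved and 0 reversed under added ones. No paired analysis was possible because each group is 1 library without a replicate number, and for the same reason no library could be left out. The planned control of empty vector cells inside the dP-mF3 mixture was not run, since neither the metadata nor the clusters assign those cells, and leaving out Scrublet's called doublets changes nothing where 0 were called. Of the classes compared, the mature dendritic cell-like one is the shallowest, at 926465 UMIs against 153137476 in dP-EV cells, and the unnamed cluster 20 had 312839. Where a rule or a set of cells was changed, the construction of the alternative gives the cause, and for the scalings and the reversals the cause was not tested.

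With a floor of 50 CPM, list members higher and lower went from 79 to 47 and from 11 to 7 for dP-EV against empty vector, from 92 to 54 and from 11 to 7 for dP-mF3 against empty vector, and from 23 to 11 higher for dP-mF3 against dP-EV. With no floor, 10 rather than 6 were lower in dP-mF3 against dP-EV. The 4-fold rule left 4 of 11 lower for dP-EV and 6 of 11 for dP-mF3 against empty vector, 9 of 23 higher and 0 of 6 lower for dP-mF3 against dP-EV, and 48 of 77 higher for dP-mF3 against spleen cells. Lists with a median of at least 2-fold went from 15 to 6, from 16 to 7 and from 18 to 11 with all members for dP-EV and dP-mF3 against empty vector and dP-mF3 against spleen cells, and from 15 to 7 with a pseudocount of 5 for dP-EV against empty vector. Members lower in dP-mF3 against empty vector went from 11 to 17 with median-of-ratios and 17 with TMM scaling, and to 19 with the mean of per-cell CPM, which gave 14 rather than 6 for dP-mF3 against dP-EV. TMM scaling moved Spi1 to 72.6 CPM and Id2 to 57.8 CPM in dP-EV cells, and Spi1, Irf8, Batf3 and Id2 to 137, 572, 22.6 and 184 CPM in the dP-mF3 mixture. Thinning moved the Ptprc and MHC class II shares to 0.557% and 40.0% in dP-EV and to 7.56% and 25.2% in dP-mF3 cells. The stricter cell filter moved the Ptprc share of mature dendritic cell-like cells from 64.4% to 86.4%. It also turned the plasmacytoid list against spleen cells, and its member Atp1b1, from -2.05 to 1.26 for dP-EV and from -2.07 to 1.25 for dP-mF3, and with all members the list median for dP-EV was 0.046. Taking all barcodes moved the KR158-derived-like share to 79.0% in the dP-EV and 88.8% in the dP-mF3 mixture, and leaving out the highest Scrublet scores moved it to 10.1% in the empty vector library. With Spi1-high cells alone, 24 members were lower in dP-mF3 against empty vector, and 28 members were lower and 4 lists passed 2-fold in dP-mF3 against dP-EV, while leaving out clusters 4 and 12 gave 9 higher, 0 lower and 0 lists there.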

Other observations

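The tests of this part and the comparisons by Spi1 level were chosen only after the results were seen.

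Lists of other cell types, meant to show cells that a mixture could hold, gave few members. Between dP-EV and empty vector cells, 2 of 3 measured factors were higher (median log2 ratio 1.55), and 3 of 7 epithelial genes were lower (median -1.36), with the secreted protein gene Wfdc2 and the keratins Krt18 and Krt19 at -1.63, -1.60 and -2.13. Of the T cell genes 1 of 3 was higher, Trbc2, which encodes a constant region of the T cell receptor, at 6.83-fold (11.2 against 1.64 CPM), with a median of 1.49 (2.21 with genes at 0 UMIs at their limit). The NK cell list had 1 measured member, the T-box factor Eomes, 4.2-fold higher. Plasmacytoid dendritic cell and neutrophil and monocyte genes had no member higher or lower of 2 and 2 (medians 1.52 and 1.05), splenic macrophage genes 1 of 3, Hmox1, which the stress list also holds (median 0.39), and no B cell or erythroid gene reached 1 CPM. Against mature dendritic cell-like cells, 2 of 4 B cell genes were lower in dP-EV cells, with a median of -2.57 (-4.09 with genes at 0 UMIs at their limit). A separate cluster of 60 dP-EV barcodes (cluster 20) was led by the neutrophil genes S100a9 and Camp and the plasmacytoid dendritic cell gene Siglech, and had Irf8 at 1004 CPM (896 to 1121) and Ptprc at 815 CPM (718 to 922), which left it without a single name.

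Against mature dendritic cell-like cells, MHC class II genes had a median log2 ratio of -2.07 in dP-EV and -3.34 in dP-mF3 Spi1-high cells, and maturation genes -5.15 and -4.22. In cluster 12, whose leading genes include the class II gene H2-DMb1, the 429 dP-EV cells had H2-Ab1 at 1529 CPM against 1531 and Cd74 at 6558 against 8308, but H2-Aa at 1272 against 3558, H2-Eb1 at 1201 against 3521 and Ciita at 103 against 261. In dP-EV Spi1-high cells, Cxcl9, a chemokine that attracts T cells, was at 156 against 1.70 CPM in cells without a Spi1 UMI, a ratio of 92.0 (72.6 to 118), with a median over cells of 0 in both. In the same cells Il11, a cytokine of fibroblasts and tumor cells, was 6.48-fold lower. In the dP-mF3 mixture Cd40, a costimulatory receptor, and Icam1, an adhesion molecule, were 46.7-fold (39.3 to 56.0) and 35.7-fold (30.3 to 42.4) higher, and Grem1 was 8.0-fold lower. The cells without a Spi1 UMI in that mixture can include empty vector cells.

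Interferon response genes were also higher in mixture cells without a Spi1 UMI, for 14 of 15 in dP-EV cells and 15 of 15 in dP-mF3 cells against empty vector cells, with medians of 4.09 and 4.56 and Ifi27l2a 178-fold and 255-fold higher. The dP-mF3 cells among these can include empty vector cells mixed into that library. A difference between libraries that arose after the cells were combined is argued against as the whole cause by 4T1-like cells. Their median was 1.62 for dP-EV and 1.22 for dP-mF3 against empty vector, although cell lines may respond unlike each other to the same handling. A batch difference in the culture, transduction or sort of the KR158 cells cannot be judged from them, since 4T1 is another line that was added. Free RNA from Spi1-high cells is argued against by Cd74, since interferon genes stood at 0.237 and 0.530 of their Spi1-high level in dP-EV and dP-mF3 cells and Cd74 at 0.0563 and 0.0992, a ratio of at least 4.22 where 1 source would keep them alike. A construct with Spi1 below detection could not be told apart from its absence in dP-EV cells without Spi1. Their puromycin resistance feature was 1.46-fold (1.11 to 1.96) that of empty vector cells, which carry it too, under the bound of 2 set for such a construct. It was 3.15-fold (2.13 to 4.83) that of 4T1-like cells, where absence was set to give at most their level. In dP-mF3 cells without Spi1 it was 2.65-fold (2.04 to 3.51) that of empty vector cells. That passes the bound, which was written for dP-EV cells only. A signal between cells in culture, such as the Ifnb1 of Spi1-high dP-mF3 cells, stays open and was not tested.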
